A study of Mus musculus with 18 samples.

How the data were processed

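Brains of 8-week-old male C57BL/6 mice were studied, 3 wild-type (WT) and 3 Ftsj1 knockout (KO), and each mouse gave 3 sequencing libraries. Per the labels, tRNA was size-selected on a gel from total RNA (total tRNA), shorter RNA of tRNA origin was taken from the same total RNA (tRNA fragments), and tRNA held in ribosomes was recovered after ribosome profiling (ribosome-contained tRNA). Per the labels, RNA was treated with AlkB, a demethylase that removes some of the base methyl groups that stop reverse transcriptase, and a 3′ adaptor was ligated before MiSeq sequencing. AlkB removes base methyl groups and leaves ribose methyl groups, the kind that FTSJ1 adds, in place.

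The authors deposited 1 table of counts, sequence read numbers per the file headers, with 147 tRNA rows, each taken as 1 mature tRNA sequence, and 18 library columns. Bowtie2 is named in the submitters' processing notes. Its version and settings, the tRNA reference set, the genome build and the rule for reads that match several tRNAs are not given in the sources used here. Reads of tRNAs with near-identical bodies can therefore have been split or shared by the counting, and no genome coordinates are given because mature tRNA sequences come from many gene copies. Library preparation measures the reads that were ligated, reverse transcribed and amplified, so a count reflects modification and structure as well as amount. PCR copies were not told apart by molecular identifiers. The table gives no read ends or lengths, so the part of a tRNA that a fragment covers is not analysed here. One ribosome-contained column is headed K3 where the others read KO, and it was taken as KO mouse 3.

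Rows were summed to 54 anticodon families, named by amino acid and anticodon, with the initiator methionine tRNA (iMet-CAT) kept apart from Met-CAT. No mitochondrial tRNA was listed. Total tRNA libraries held 1505291 to 2000422 reads, ribosome-contained libraries 406764 to 672127 reads and fragment libraries 85323 to 151056 reads. A share is the reads of a family as a percentage of all tRNA reads of its library, given as mean ± SD over mice. No spike-in is used here, so every value is relative to the other tRNAs of the same library.

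Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling factors, filterByExpr with a minimum count of 10, Benjamini-Hochberg adjustment, threshold 0.05). The KO and WT groups were compared within each library type over its 6 libraries. The difference of the KO effect between library types, and the library types within WT, were tested in fits over 12 libraries with 4 groups. The filter left 49, 49 and 46 families in the total, ribosome-contained and fragment fits, 51 in the fits of ribosome-contained with total libraries, and 49 in those of fragment with total libraries. The common biological coefficient of variation was 0.0592, 0.0923 and 0.0688 in the first 3 fits. The standard error of a log2 fold change was its absolute value divided by the square root of the F statistic. Shares were compared with two-sided exact permutation tests in SciPy 1.17.1, where 3 mice against 3 cannot give a p under 0.1. Tables were handled with pandas 2.3.3 in Python 3.11.15 and plots drawn with matplotlib 3.10.9.

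The comparisons, the tests, the alternatives and 11 tRNA lists were fixed before the data were examined. The lists, drawn from general knowledge of tRNA modification, were the FTSJ1 wobble list (Phe-GAA, Trp-CCA, Leu-CAA, Leu-TAA), a wider FTSJ1 list that adds tRNAs reported as targets at the first base of the anticodon loop, tRNAs with inosine at the wobble base, tRNAs with a wobble uridine of the kind modified through Elongator, the queuosine tRNAs, the DNMT2 targets, tRNAs often cleaved in the anticodon loop, tRNAs with a threonylcarbamoyl or isopentenyl adenosine beside the anticodon, tRNAs with a long variable arm, the brain-enriched Arg-TCT family, and the methionine tRNAs. The lists overlap. The 10 lists with at least 2 members were tested with camera in limma 3.58.1 on log2 CPM, counts scaled to a common library size (prior count 2, preset correlation 0.01), again with an estimated correlation, and with fry, and list p-values were adjusted over the 10 lists of a comparison.

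The text names, in each comparison, the 4 members of the FTSJ1 wobble list, up to 10 families higher and 10 lower with the largest fold change past the threshold, the 3 with the largest change in a direction where fewer than 3 passed, and the 2 members of a described list with the largest change. The remaining families appear only in counts.

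The procedure was tested on simulated data drawn from the means and library sizes of each comparison, in 30 simulations with 8 changed families each. Changed families were drawn from those with a mean count of at least 100, and changed 1.5-fold or 2-fold. Recovery of smaller changes, or of changes in scarcer families, was not tested. In the 3 comparisons of KO with WT, 1.5-fold changes were recovered in 100%, 100% and 99.2% of cases for total, ribosome-contained and fragment libraries. For the difference of the KO effect, recovery of 1.5-fold changes was 79.2% between ribosome-contained and total libraries and 85.0% between fragment and total libraries, and unchanged families were called in 0.853% and 5.05% of cases.

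The alternatives were DESeq2 1.42.0 and limma-voom in place of edgeR, DESeq2's size factors in edgeR, total reads as the only scaling, total reads without Phe-GAA, no filter, a mean count of at least 100, the table's own rows, all 18 libraries in 1 fit, a block for the replicate number or mouse, and leaving out each mouse in turn. TMM factors computed within each library type, and list tests without each mouse and with the mouse or replicate number as a block, were added after the data had been examined. Fits of the table's own rows give no value for a family, so they entered only the counts of calls. They are not among the 15 alternative settings (16 for a difference of the KO effect) given for named tRNAs. Libraries of the same mouse are tied across library types by the mouse named in the labels. Their deviations from the group means correlated with r between -0.34 and 0.64 for total with ribosome-contained libraries and between -0.13 and 0.32 for total with fragment libraries. Within a group no library was a copy of another, since the chi-square per degree of freedom between pairs of replicates ranged from 3.31 to 126 over 18 pairs.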

Results

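FTSJ1 adds a methyl group to the ribose of anticodon loop nucleotides in a small set of tRNAs, and its loss in people is linked to X-linked intellectual disability. The series compared the tRNA of Ftsj1 KO and WT mouse brain in 3 forms: intact tRNA of the whole tissue, tRNA held in ribosomes, and fragments of tRNA. There were 3 male mice of each genotype, aged 8 weeks, and 6 libraries of each form, 18 in all. Total tRNA libraries held 1505291 to 2000422 reads, ribosome-contained libraries 406764 to 672127 and fragment libraries 85323 to 151056. Ftsj1 mRNA lies outside these libraries, and the knockout itself was not checked here.

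The first comparison asked which intact tRNAs differ in amount in KO brain. Phe-GAA, the phenylalanine tRNA and the best known FTSJ1 target, fell from 2.58% ± 0.127 of total tRNA reads in WT to 1.09% ± 0.0933 in KO (SD, n = 3 mice each; exact permutation p = 0.1, the smallest possible). Its log2 fold change was -1.28 (SE 0.07, adjusted p = 9.1e-19 in edgeR's quasi-likelihood test), a 2.43-fold decrease. Of 49 tRNAs tested, 3 others passed: Trp-CCA, the tryptophan tRNA, and Ala-AGC, an alanine tRNA with a wobble inosine, fell by 0.22 each on the log2 scale (SE 0.06 each, adjusted p = 0.018 and 0.016), and Arg-CCT, an arginine tRNA, rose by 0.23 (SE 0.06, adjusted p = 0.011).

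Within the FTSJ1 wobble list 2 of the 4 tRNAs fell, also when adjusted over the list alone, and the leucine tRNAs Leu-CAA (log2 fold change 0.01, SE 0.06) and Leu-TAA (-0.04, SE 0.08) did not pass. Tested as a list, these 4 were lower (camera adjusted p = 0.0319, and adjusted p = 0.345 with an estimated correlation). Their mean log2 fold change was -0.38 and their median -0.13, with Phe-GAA farthest from 0 at -1.28. The camera call of the list ended without WT mouse 2 (adjusted p = 0.0873), KO mouse 1 (0.0805) or KO mouse 3 (0.145). In the wider FTSJ1 list the same 2 of 12 fell and none rose; adjusted over the list alone, 1 rose and 2 fell (camera adjusted p = 0.437). Among the 8 tRNAs with a wobble inosine 1 fell, Ala-AGC, while Ile-AAT was at -0.13 (SE 0.07). Arg-CCT was the 1 of 17 tRNAs with a modified adenosine beside the anticodon that rose, and Thr-CGT was at 0.15 (SE 0.06). No member passed among the 14 wobble uridine tRNAs (Pro-TGG 0.41, SE 0.19, and Gln-TTG 0.20, SE 0.07), the 4 queuosine tRNAs (Asp-GTC -0.21, SE 0.09, and Tyr-GTA 0.13, SE 0.07), the 3 DNMT2 targets (Gly-GCC -0.01, SE 0.06), the 9 tRNAs often cleaved in the anticodon loop (Gly-CCC 0.08, SE 0.06) or the 10 long-arm tRNAs (Leu-TAG 0.16, SE 0.07, and SeC-TCA 0.15, SE 0.07). Camera adjusted p-values of these lists lay between 0.437 and 0.535. Neither methionine tRNA passed (iMet-CAT 0.03, Met-CAT -0.06, SE 0.06 and 0.07; camera adjusted p = 0.805), nor did Arg-TCT, a family with a brain-enriched member (0.05, SE 0.06). Pro-GGG, a scarce proline tRNA with 8 to 27 reads in WT and 21 to 86 in KO libraries, had a log2 fold change of 1.39 (SE 0.51) that did not pass (adjusted p = 0.076).

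Phe-GAA was called under each of the 15 alternative settings, whereas Arg-CCT was called in 10, Ala-AGC in 9 and Trp-CCA in 8 of them. The call of Trp-CCA ended, among others, with DESeq2, with scaling by total reads and without KO mouse 3, WT mouse 1 or WT mouse 3, and its share of total reads was 1.55% ± 0.117 in WT and 1.36% ± 0.0841 in KO (SD, n = 3 mice each; exact permutation p = 0.2). The count of 4 became 1 without WT mouse 1 or WT mouse 3, 2 without KO mouse 2, 7 without KO mouse 3 and 9 without KO mouse 1, and scaling by total reads alone left 1 higher and 1 lower in place of 1 and 3.

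**Figure D1:**
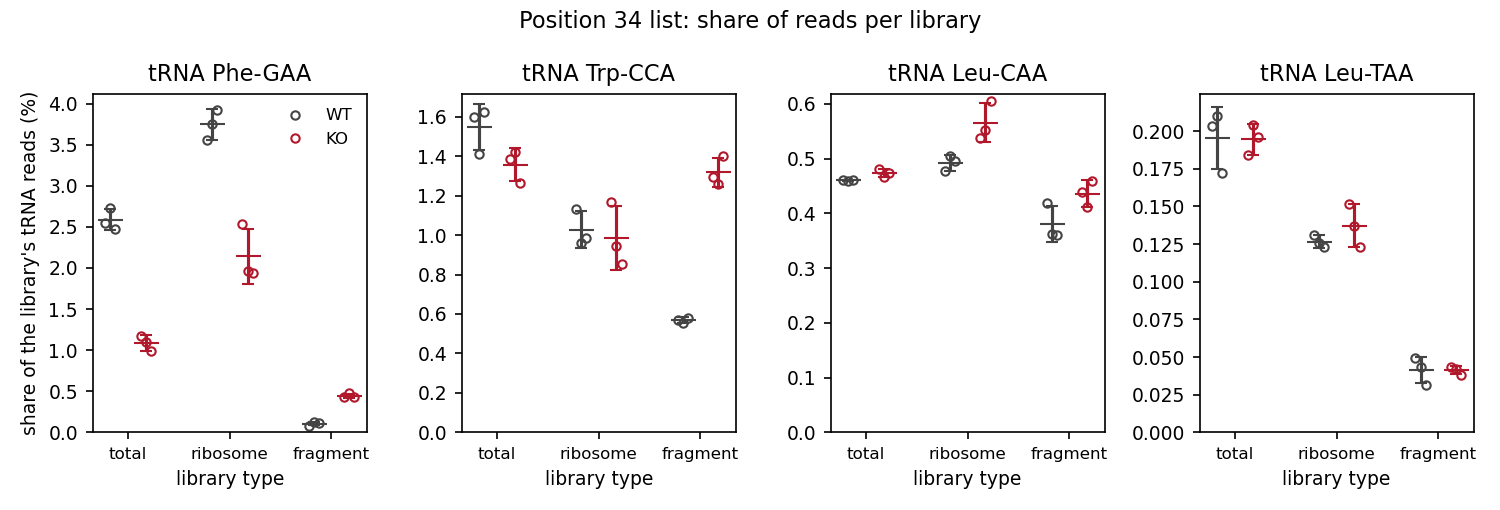
Share of each library's tRNA reads (percent, y axis) taken by the 4 tRNAs of the FTSJ1 wobble list in total, ribosome-contained and fragment libraries (x axis) of WT (grey) and KO (red) brain; circles are mice, and the line and bars are the mean and SD (n = 3). Phe-GAA fell from 2.58% to 1.09% in total tRNA and rose from 0.105% to 0.443% among fragments, where Trp-CCA rose from 0.569% to 1.32%.

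In ribosomes Phe-GAA was again lower in KO, 2.14% ± 0.337 of reads against 3.75% ± 0.185 in WT (SD, n = 3 mice each; exact permutation p = 0.1). The log2 fold change was -0.80 (SE 0.10, adjusted p = 0.0012 in edgeR's quasi-likelihood test), a 1.75-fold decrease. Arg-TCG, an arginine tRNA on the wider FTSJ1 list, fell from 2.00% ± 0.0285 to 1.55% ± 0.0409 (log2 fold change -0.37, SE 0.06, adjusted p = 0.007), and Leu-TAG, a leucine tRNA, rose from 0.593% ± 0.0474 to 0.880% ± 0.0866 (0.57, SE 0.11, adjusted p = 0.007). In all, 5 of 49 tRNAs rose and 6 fell. The other tRNAs that rose were the serine tRNAs Ser-GCT (0.37, SE 0.10), Ser-AGA (0.33, SE 0.10) and Ser-TGA (0.28, SE 0.08) and the histidine tRNA His-GTG (0.27, SE 0.07). The others that fell were Gly-ACC (-0.35, SE 0.07), Lys-CTT (-0.31, SE 0.07), Ala-AGC (-0.27, SE 0.06) and Gly-TCC (-0.25, SE 0.07). Adjusted p-values of these 8 lay between 0.010 and 0.038.

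Of the 10 tRNAs with a long variable arm, which are those for serine, leucine and selenocysteine, 4 rose in KO ribosomes (Leu-TAG, Ser-GCT, Ser-AGA and Ser-TGA) and none fell; adjusted over the list alone, 6 rose. The median log2 fold change of the list was 0.29, and SeC-TCA was at -0.01 (SE 0.35). The list passed camera with the preset correlation (adjusted p = 0.00036) and did not pass with an estimated one (adjusted p = 0.834 with an estimated correlation). Without KO mouse 1, 8 members rose, and without KO mouse 2, KO mouse 3, WT mouse 1, WT mouse 2 or WT mouse 3 only 1 did, Leu-TAG. Their summed share was 12.8% ± 0.702 in WT and 16.1% ± 1.45 in KO (SD, n = 3 mice each; exact permutation p = 0.1). In total tRNA the same mice had 13.5% ± 0.259 and 14.3% ± 1.30 (exact permutation p = 0.4). In the FTSJ1 wobble list 1 of 4 fell, Phe-GAA, and Trp-CCA (-0.05, SE 0.11), Leu-CAA (0.20, SE 0.08) and Leu-TAA (0.12, SE 0.10) did not pass; adjusted over the list alone the count was also 1. The wider FTSJ1 list had 2 that fell of 12, Phe-GAA and Arg-TCG, both overall and adjusted over the list alone.

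Of the 14 wobble uridine tRNAs 2 rose (Leu-TAG and Ser-TGA) and 2 fell (Arg-TCG and Gly-TCC), with 2 and 3 adjusted over the list alone, and of the 17 with a modified adenosine beside the anticodon 3 rose (Ser-GCT, Ser-AGA and Ser-TGA) and 1 fell (Lys-CTT), with 3 and 2 adjusted over the list alone. Of the 8 wobble inosine tRNAs 1 rose (Ser-AGA) and 1 fell (Ala-AGC), and Leu-AAG was at 0.33 (SE 0.12) without passing. Of the 9 often cleaved tRNAs 1 rose (His-GTG) and 1 fell (Lys-CTT). His-GTG was also the 1 of 4 queuosine tRNAs that rose, with Asp-GTC at 0.20 (SE 0.18). None of the 3 DNMT2 targets (Val-AAC 0.13, SE 0.09), the methionine tRNAs (Met-CAT -0.15 and iMet-CAT -0.03, SE 0.09 each) or Arg-TCT (0.05, SE 0.09) passed. Camera adjusted p was 0.866 for the queuosine list and 0.99 for every tested list other than it and the long-arm list.

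Phe-GAA, Arg-TCG and Leu-TAG were called in all 15 alternative settings, and the other 8 in 8 to 12 of them. The count of 11 became 22 without KO mouse 1, 7 without KO mouse 3, 4 without WT mouse 3, and 3 without KO mouse 2, WT mouse 1 or WT mouse 2.

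Fragments of Phe-GAA and Trp-CCA were more abundant in KO brain, although intact Phe-GAA had fallen. Phe-GAA fragments rose 4.23-fold, from 0.105% ± 0.0217 of fragment reads (93 to 115 reads per library) to 0.443% ± 0.0256 (448 to 650 reads; SD, n = 3 mice each; exact permutation p = 0.1). The log2 fold change was 2.08 (SE 0.15, adjusted p = 1.6e-16 in edgeR's quasi-likelihood test). Trp-CCA fragments rose 2.32-fold, from 0.569% ± 0.0133 to 1.32% ± 0.0746 (log2 fold change 1.21, SE 0.09, adjusted p = 1.6e-16; exact permutation p = 0.1 for the share, n = 3 mice each). Fragments of Ser-AGA, a serine tRNA, fell 2.01-fold (log2 fold change -1.01, SE 0.17, adjusted p = 2.5e-06), with 217 to 369 reads in WT and 126 to 205 in KO libraries. Fragments of the glutamine tRNA Gln-CTG fell from 4.61% ± 0.0907 to 3.30% ± 0.0601 (-0.48, SE 0.06, adjusted p = 1.1e-09).

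In all, 9 of 46 tRNAs rose and 3 fell among fragments. Smaller rises were found for the proline tRNA Pro-AGG (0.37, SE 0.06), the cysteine tRNA Cys-GCA (0.34, SE 0.06), Ala-AGC (0.33, SE 0.07), the asparagine tRNA Asn-GTT (0.32, SE 0.10), Arg-CCG (0.23, SE 0.08), Thr-CGT (0.22, SE 0.07) and Arg-CCT (0.16, SE 0.06), and Gly-ACC fell (-0.25, SE 0.09). Their adjusted p-values lay between 5.3e-06 and 0.032. In the FTSJ1 wobble list 2 of 4 rose, also when adjusted over the list alone, and Leu-CAA (0.19, SE 0.12) and Leu-TAA (-0.01, SE 0.17, 33 to 66 reads per library) did not pass; the list was higher (camera adjusted p = 0.0206; adjusted p = 0.294 with an estimated correlation). In the wider FTSJ1 list 4 of 12 rose (Phe-GAA, Trp-CCA, Cys-GCA and Arg-CCG) and 1 fell (Gln-CTG), with 4 and 2 adjusted over the list alone (camera adjusted p = 0.451).

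Among the 9 tRNAs often cleaved in the anticodon loop no fragment passed, and His-GTG (-0.20, SE 0.13) and Glu-TTC (-0.19, SE 0.08) were the members farthest from 0. Of the 8 wobble inosine tRNAs 2 rose (Pro-AGG and Ala-AGC) and 1 fell (Ser-AGA). Of the 17 with a modified adenosine beside the anticodon 3 rose (Asn-GTT, Thr-CGT and Arg-CCT) and 1 fell (Ser-AGA). Of the 10 long-arm tRNAs only Ser-AGA fell, and Ser-CGA was at -0.32 (SE 0.16). Asn-GTT was the 1 of 4 queuosine tRNAs that rose, with His-GTG next. None passed among 13 wobble uridine tRNAs (Ser-TGA -0.29, SE 0.16, and Arg-TCG -0.29, SE 0.12), 3 DNMT2 targets (Gly-GCC -0.10, SE 0.06, and Val-AAC 0.07, SE 0.15) and Arg-TCT (0.06, SE 0.13). Neither methionine tRNA passed (iMet-CAT -0.17, SE 0.07; Met-CAT 0.01, SE 0.06), and adjusted over the list alone 1 fell. Camera adjusted p-values of these lists lay between 0.451 and 0.838.

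Phe-GAA, Trp-CCA, Ser-AGA, Gln-CTG, Pro-AGG, Cys-GCA and Ala-AGC were called in all 15 alternative settings. Asn-GTT lost its call in 2 of them, Arg-CCG and Thr-CGT in 6 each, Gly-ACC in 7 and Arg-CCT in 8, each of the 5 among others without KO mouse 3. The count of 12 became 7 without KO mouse 3.

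**Figure D2:**
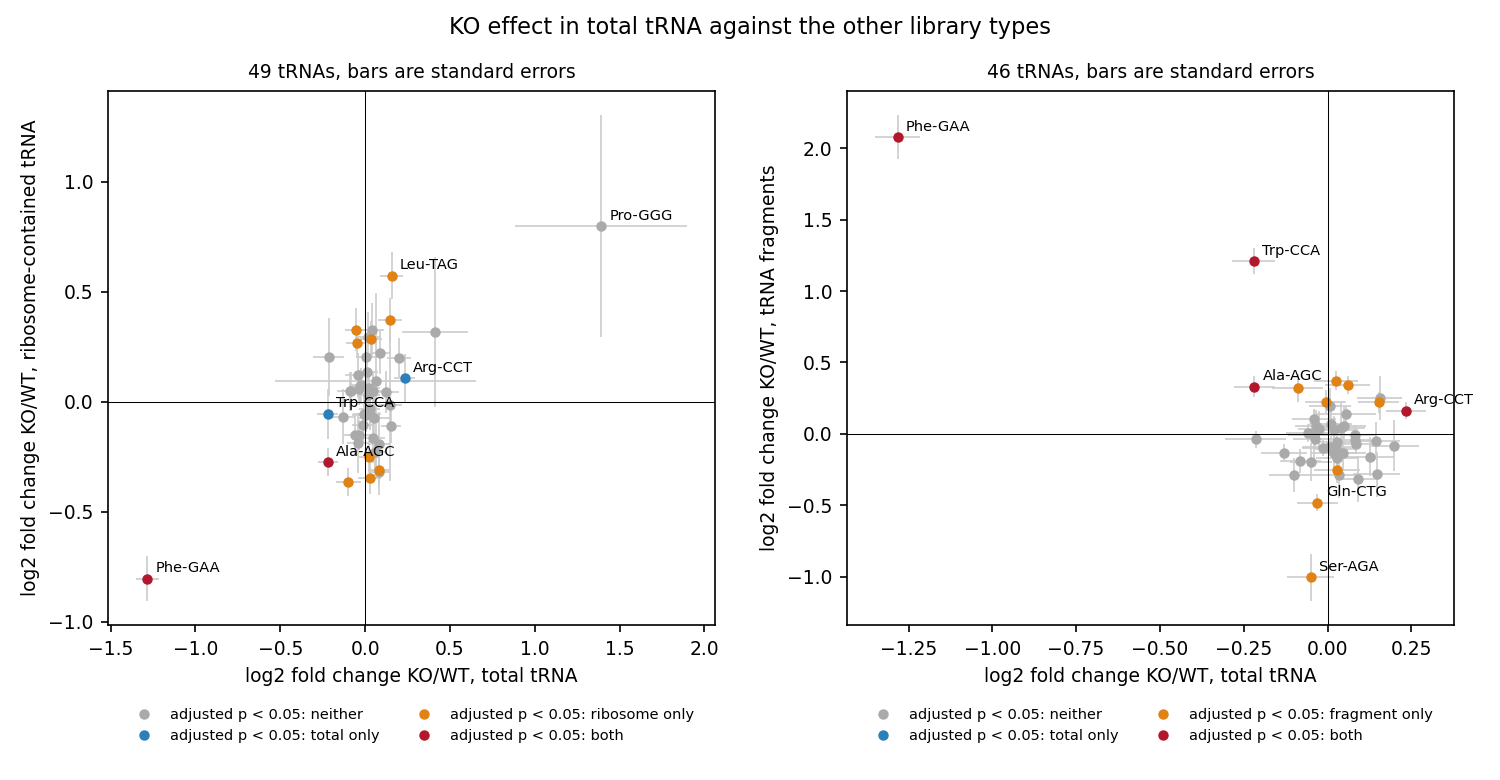
Log2 fold change KO/WT of each tRNA in total tRNA (x axis) against that in ribosome-contained tRNA (left, 49 tRNAs) and in tRNA fragments (right, 46 tRNAs); points are tRNAs, bars are standard errors (3 mice per group), and colours give the library types in which adjusted p was under 0.05. Phe-GAA lies at -1.28 in total tRNA, -0.80 in ribosomes and 2.08 among fragments, and Trp-CCA at 1.21 among fragments.

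Whether the KO effect differs between ribosome-contained and total tRNA was tested as an interaction. Phe-GAA had fallen less in ribosomes, by a log2 difference of 0.50 (SE 0.15), just short of the threshold (adjusted p = 0.0501 in edgeR's quasi-likelihood test; 0.0578 with the mouse as a block). No tRNA of 51 passed in edgeR, and 11 did at an unadjusted p under 0.05. DESeq2 called 2 lower and 0 higher, whereas limma-voom called 2 higher and 0 lower, so the 2 tools shared no call. Trp-CCA (0.20, SE 0.14), Leu-CAA (0.22, SE 0.15) and Leu-TAA (0.20, SE 0.18) did not pass. The next largest positive differences were Asp-GTC (0.46, SE 0.20) and Leu-TAG (0.45, SE 0.15), and the largest negative ones were the scarce Cys-ACA (-2.15, SE 1.07), Ile-GAT (-1.25, SE 1.20) and Pro-GGG (-0.57, SE 0.76), with adjusted p between 0.11 and 0.73.

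The long-arm tRNAs had a higher KO effect in ribosomes than in total tRNA as a list (median log2 difference 0.27, 0 of 10 past the test over all tRNAs, 2 adjusted over the list alone). Camera gave adjusted p = 0.0031, or 0.0101 with the mouse as a block, and adjusted p = 0.585 with an estimated correlation. The FTSJ1 wobble list (median 0.21, 0 of 4 past the test, 1 adjusted over the list alone) did not pass without the block (camera adjusted p = 0.105) and did with it (0.0445; adjusted p = 0.792 with the block and an estimated correlation). None of the remaining lists passed, with camera adjusted p between 0.23 and 0.677, and adjusted over the list alone 1 tRNA rose in the wider FTSJ1 list (Phe-GAA 0.50; Cys-GCA -0.26, SE 0.14), 1 in the queuosine list (His-GTG 0.35, SE 0.13) and 1 among the often cleaved tRNAs, where 1 also fell (Lys-CTT -0.37, SE 0.14).

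The count of 0 became 13 without KO mouse 1, 9 without KO mouse 3, 5 without WT mouse 1 and 1 without WT mouse 3. It was 7, all lower, with DESeq2's size factors, 10 (4 higher, 6 lower) with TMM within each library type and 11 (4 higher, 7 lower) with total reads, which moved the median of all tRNAs from -0.02 to -0.15, -0.06 and -0.09.

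Between fragments and total tRNA the KO effect differed most for Phe-GAA, by 3.24 on the log2 scale (SE 0.14, adjusted p = 2e-11 in edgeR's quasi-likelihood test), and for Trp-CCA, by 1.31 (SE 0.10, adjusted p = 2.8e-08). The ratio of the fragment share to the total share of Phe-GAA was 0.0407 ± 0.00757 in WT and 0.409 ± 0.0369 in KO mice (SD, n = 3 each; exact permutation p = 0.1). For Trp-CCA the ratio was 0.369 ± 0.0204 and 0.976 ± 0.119 (exact permutation p = 0.1, n = 3 each). For Leu-CAA (0.827 ± 0.0722 and 0.920 ± 0.0455, exact permutation p = 0.2, n = 3 each) and Leu-TAA (0.211 ± 0.0289 and 0.213 ± 0.0219, exact permutation p = 0.9, n = 3 each) the interaction did not pass (0.06, SE 0.10, and -0.09, SE 0.22). Ala-AGC, which fell in total tRNA and rose among fragments, differed by 0.43 (SE 0.08, adjusted p = 0.0015).

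Of 49 tRNAs 5 had a higher and 11 a lower KO effect among fragments, around a median of -0.19 for all tRNAs. Asn-GTT (0.29, SE 0.09) and Pro-AGG (0.22, SE 0.07) were the other higher ones. The largest negative differences among those past the threshold were Ser-AGA (-1.08, SE 0.20, adjusted p = 0.0012), Gln-CTG (-0.57, SE 0.08, adjusted p = 3.1e-05), SeC-TCA (-0.55, SE 0.18), Ser-CGA (-0.53, SE 0.15), Ser-TGA (-0.45, SE 0.16), Tyr-GTA (-0.41, SE 0.10) and Gly-ACC (-0.40, SE 0.09). Gly-CCC (-0.28, SE 0.10), Gly-TCC (-0.25, SE 0.09), Thr-TGT (-0.25, SE 0.08) and Glu-CTC (-0.22, SE 0.08; named after its value was seen, and without a call in 13 of 16 alternative settings) were the remaining ones. With the mouse as a block, Pro-AGG (adjusted p = 0.0693), Ser-TGA (0.0606), Gly-CCC (0.0606), Gly-TCC (0.0796) and Thr-TGT (0.0693) no longer passed. In simulation the fit without a block called 5.05% of unchanged families, so the smaller differences here may include false calls.

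The FTSJ1 wobble list had 2 of 4 higher, also when adjusted over the list alone, and was the one list whose call held with an estimated correlation (camera adjusted p = 0.0012; adjusted p = 0.0282 with an estimated correlation). With the mouse as a block these were 0.0016 and 0.142. The wider FTSJ1 list had 2 higher (Phe-GAA and Trp-CCA) and 2 lower (Gln-CTG and Gly-CCC) of 12, the same numbers adjusted over the list alone (camera adjusted p = 0.353). Of the 10 long-arm tRNAs 4 were lower (Ser-AGA, SeC-TCA, Ser-CGA and Ser-TGA), 4 also adjusted over the list alone, and of the 17 with a modified adenosine 5 were lower and 1 higher, with 8 and 1 adjusted over the list alone. Of the 14 wobble uridine tRNAs 3 were lower, with 0 adjusted over the list alone, and Pro-TGG was at -0.92 (SE 0.82). Wobble inosine tRNAs had 2 higher and 1 lower of 8 (2 and 2 adjusted over the list alone), queuosine tRNAs 1 higher and 1 lower of 4, and often cleaved tRNAs 2 lower of 9 (0 adjusted over the list alone; Val-CAC -0.28, SE 0.11, did not pass). No DNMT2 target (Gly-GCC -0.21, SE 0.08, and Val-AAC -0.06, SE 0.12), methionine tRNA (iMet-CAT -0.32, SE 0.12, which was lower adjusted over the list alone and with the mouse as a block, adjusted p = 0.0348, and Met-CAT -0.06, SE 0.09) or Arg-TCT (-0.11, SE 0.11) passed, and camera adjusted p of the lists after the first was 0.353 to 0.926.

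The negative calls depended on the scaling: TMM within each library type moved the median to -0.03 and left 6 higher and 2 lower, and total reads gave 6 and 5. Phe-GAA, Trp-CCA, Ala-AGC, Gln-CTG and Ser-AGA were called in all 16 alternative settings, and the count of 16 became 9 without KO mouse 2 and 8 without WT mouse 1.

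Within WT brain, the ribosome-contained pool differed in makeup from total tRNA. The initiator tRNA iMet-CAT, which starts translation, made up 1.92% ± 0.119 of total and 4.66% ± 0.318 of ribosome-contained reads (log2 fold change 1.23, SE 0.10, adjusted p = 5.1e-16 in edgeR's quasi-likelihood test), whereas the elongator Met-CAT did not differ past the threshold (0.07, SE 0.10). SeC-TCA, which inserts selenocysteine at a few recoded stop codons, was 39.1-fold lower in ribosomes (-5.29, SE 0.18, adjusted p = 2.3e-34), at 50 to 89 reads per library. Phe-GAA was higher in ribosomes (0.48, SE 0.10), Trp-CCA (-0.64, SE 0.10) and Leu-TAA (-0.68, SE 0.13) were lower, and Leu-CAA did not pass (0.05, SE 0.11).

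In all, 19 of 51 tRNAs were higher in ribosomes and 19 lower. The largest fold changes among the higher ones were those of Ile-GAT (2.91, SE 0.82), Cys-ACA (2.45, SE 0.83) and Ala-GGC (1.88, SE 0.47), all on few reads, followed by Gly-TCC (1.52, SE 0.09), iMet-CAT, Gly-ACC (1.19, SE 0.11), Ala-AGC (0.94, SE 0.09), Pro-TGG (0.90, SE 0.26), Gly-GCC (0.89, SE 0.10) and Val-CAC (0.78, SE 0.11). Cys-ACA lost its call without WT mouse 1 or WT mouse 2, and Pro-TGG without WT mouse 2. The lowest after SeC-TCA were Ser-CGA (-1.41, SE 0.11), Thr-CGT (-1.26, SE 0.10), Arg-TCG (-1.18, SE 0.10) and Arg-CCG (-1.02, SE 0.10), then Lys-TTT (-0.77, SE 0.12), Arg-CCT (-0.77, SE 0.10), Ser-TGA (-0.73, SE 0.10), Cys-GCA (-0.72, SE 0.10) and Leu-TAG (-0.69, SE 0.11).

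No list passed camera in this comparison (adjusted p between 0.342 and 0.956). Counts adjusted over the list alone equalled those over all tRNAs. Of the 17 tRNAs with a modified adenosine 3 were higher and 9 lower in ribosomes, of the 10 long-arm tRNAs 2 and 5, of the 14 wobble uridine tRNAs 3 and 6, and of the 12 on the wider FTSJ1 list 4 and 6. Of the 9 often cleaved tRNAs 4 were higher and 3 lower, and of the 8 wobble inosine tRNAs 4 and 3, with Val-AAC at 0.70 (SE 0.10). Of the DNMT2 targets 2 of 3 were higher (Gly-GCC and Val-AAC). Of the 4 queuosine tRNAs Tyr-GTA was higher (0.54, SE 0.11) and His-GTG lower (-0.58, SE 0.09), and Arg-TCT was higher (0.62, SE 0.10).

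**Figure D3:**
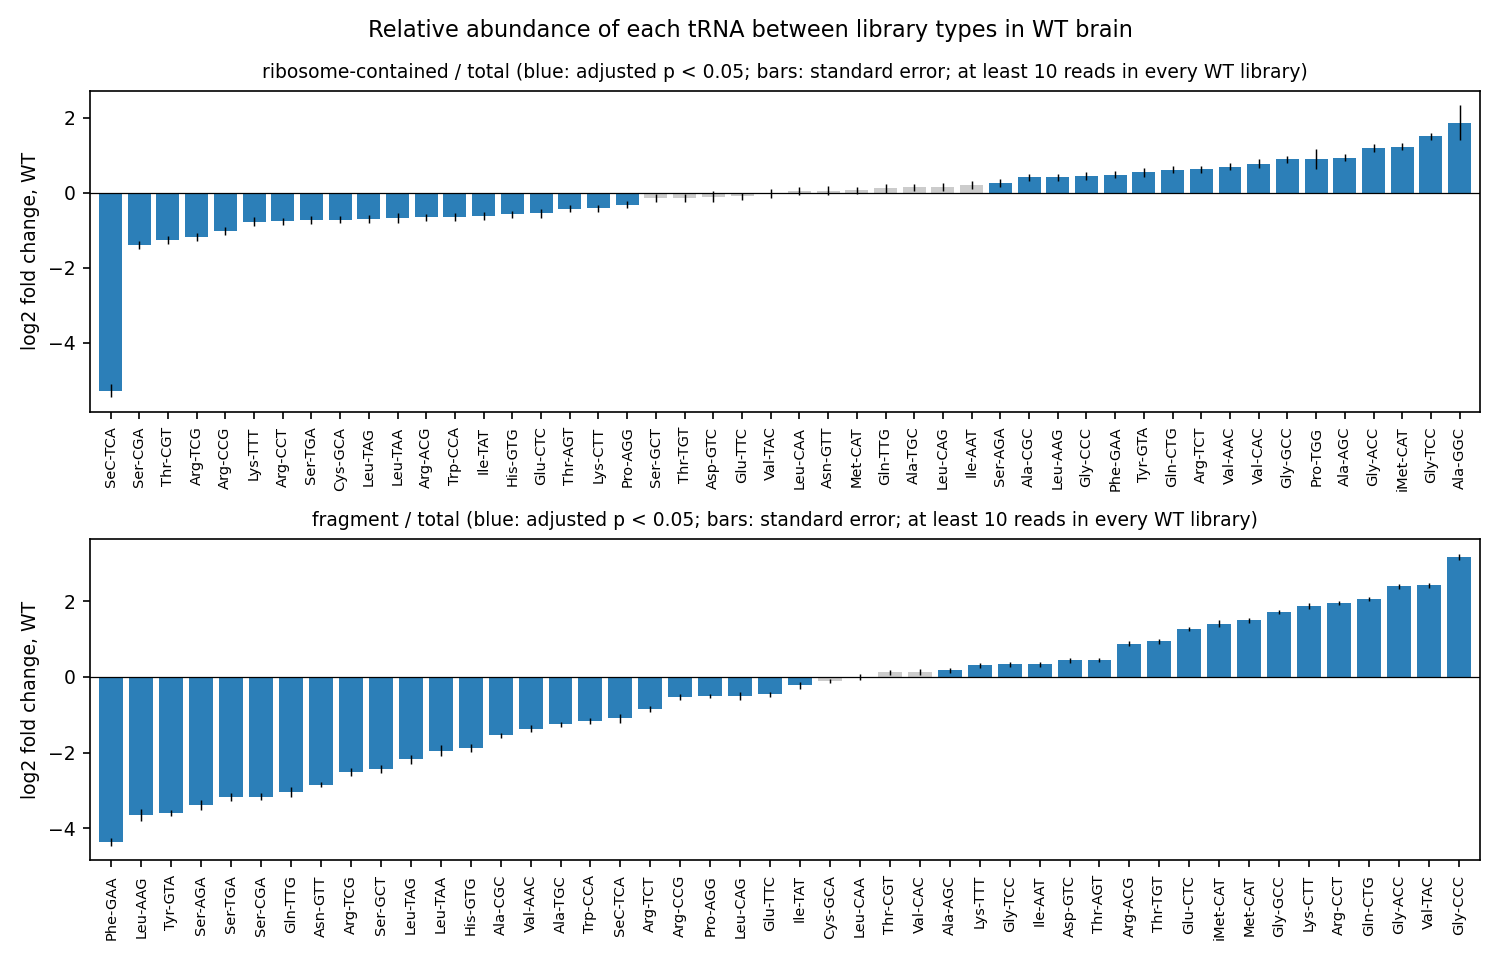
Log2 fold change of each tRNA in WT brain between ribosome-contained and total libraries (top) and between fragment and total libraries (bottom), for tRNAs with at least 10 reads in every WT library of the 2 types; bars are standard errors (n = 3 mice) and blue marks adjusted p under 0.05. SeC-TCA lies at -5.29 in ribosomes, and Gly-CCC at 3.18 and Phe-GAA at -4.36 among fragments.

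The fragment pool of WT brain was led by Glu-CTC, the glutamate tRNA known to be cleaved often in its anticodon loop, with 14.2% ± 0.306 of fragment reads against 7.14% ± 0.296 of total reads. Relative to total tRNA, fragments were most enriched for the glycine tRNA Gly-CCC (log2 fold change 3.18, SE 0.08, adjusted p = 1.5e-15 in edgeR's quasi-likelihood test), Val-TAC (2.42, SE 0.06), Gly-ACC (2.39, SE 0.06), Gln-CTG (2.07, SE 0.06), Arg-CCT (1.95, SE 0.06), Lys-CTT (1.87, SE 0.08) and Gly-GCC (1.71, SE 0.06), with Met-CAT (1.495, SE 0.07), iMet-CAT (1.41, SE 0.09) and Glu-CTC (1.27, SE 0.06) next. Phe-GAA was the most depleted tRNA, 20.5-fold lower (-4.36, SE 0.11, adjusted p = 1.5e-15). Leu-AAG (-3.66, SE 0.16), Tyr-GTA (-3.59, SE 0.07), Ser-AGA (-3.39, SE 0.14), Ser-TGA (-3.18, SE 0.11), Ser-CGA (-3.17, SE 0.10), Gln-TTG (-3.05, SE 0.14), Asn-GTT (-2.85, SE 0.07), Arg-TCG (-2.52, SE 0.11) and Ser-GCT (-2.43, SE 0.11) followed.

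Long-arm tRNAs were scarce among fragments, with 9 of 10 lower and none higher, a median of -2.31 and a summed share of 2.59% ± 0.126 (SD, n = 3) against 13.5% in total tRNA; the list did not pass (camera adjusted p = 0.0614; adjusted p = 0.525 with an estimated correlation). In the FTSJ1 wobble list 3 of 4 were lower, Trp-CCA at -1.17 (SE 0.07) and Leu-TAA at -1.96 (SE 0.15) besides Phe-GAA, and Leu-CAA (0.00, SE 0.07) did not pass. Of the 9 often cleaved tRNAs 5 were higher and 3 lower, the latter including His-GTG (-1.88, SE 0.10) and Val-AAC (-1.37, SE 0.08). The wider FTSJ1 list had 3 higher and 7 lower of 12, the wobble uridine tRNAs 4 and 9 of 14, the modified adenosine tRNAs 8 and 8 of 17, the wobble inosine tRNAs 4 and 4 of 8, the queuosine tRNAs 1 and 3 of 4 and the DNMT2 targets 2 and 1 of 3. Both methionine tRNAs were higher, and Arg-TCT was lower (-0.85, SE 0.08). Counts adjusted over the list alone were the same, and camera adjusted p of these lists was 0.348 to 0.994.

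In all, 18 of 49 tRNAs were higher and 24 lower, around a median of -0.46. DESeq2's size factors gave 22 and 21 around -0.14, and total reads gave 14 and 27 around -0.73, under which Leu-CAA was lower (-0.27).

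Across tRNAs, which are not independent replicates, the KO effects in total and ribosome-contained libraries had a Pearson r of 0.65 and a Spearman rho of 0.26 over 49 tRNAs. Total and fragment effects had an r of -0.69 and a rho of -0.08 over 46 tRNAs, and ribosome-contained and fragment effects an r of -0.43 and a rho of -0.10. Without Phe-GAA, Trp-CCA, Leu-CAA and Leu-TAA the 3 values of r were 0.54, 0.07 and -0.14. The negative r between total tRNA and fragments was thus absent among the remaining tRNAs. In total tRNA and fragments, Phe-GAA lay at -1.28 and 2.08 and Trp-CCA at -0.22 and 1.21. Leu-CAA (0.01 and 0.19) and Leu-TAA (-0.04 and -0.01) passed in neither. These tRNAs were left out only together, so the part of each in the negative r was not tested. The library types share mice, and no p-value was computed.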

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

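The difference of the KO effect between fragments and intact tRNA was a comparison fixed before the data were examined, and the tests of explanations in this part were chosen only after the result was seen.

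The 15 named tRNAs past the threshold for a different KO effect in fragment and total libraries are singled out because the effect of the same genotype contrast differed between library types in the interaction test. The log2 difference, fragment minus total, was 3.24 for Phe-GAA, 1.31 for Trp-CCA, 0.43 for Ala-AGC, 0.29 for Asn-GTT and 0.22 for Pro-AGG. It was -1.08 for Ser-AGA, -0.57 for Gln-CTG, -0.55 for SeC-TCA, -0.53 for Ser-CGA, -0.45 for Ser-TGA, -0.41 for Tyr-GTA, -0.40 for Gly-ACC, -0.28 for Gly-CCC, -0.25 for Gly-TCC and -0.25 for Thr-TGT. Of these, Phe-GAA, Trp-CCA, Ala-AGC, Ser-AGA and Gln-CTG were called under all 16 alternative settings, Tyr-GTA and Gly-ACC under 13 each, Asn-GTT under 12, Ser-CGA under 10, Pro-AGG under 9, SeC-TCA under 7, Thr-TGT under 5, Gly-TCC under 4, Gly-CCC under 3 and Ser-TGA under 1 of them.

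The pattern weighed here is that fragments of Phe-GAA and Trp-CCA rose in KO brain while intact Phe-GAA fell; the smaller fall of intact Trp-CCA was called in 8 of 15 alternative settings and is not relied on. The values argue against 1 explanation, that loss of the wobble methyl group by itself makes any listed tRNA break during preparation. It would raise fragments of Leu-CAA and Leu-TAA too, and these had a mean log2 fold change of 0.093. Leu-CAA was at 0.19 (SE 0.12) and Leu-TAA at -0.01 (SE 0.17, 33 to 66 reads per library). A rise as large as that of Trp-CCA (1.21) is argued against, and a small one is not. This holds only if Leu-CAA and Leu-TAA lose the methyl group in KO, which was not measured. Easier reverse transcription of the fragments stays open, because counts per tRNA hold no read ends that would separate it from abundance (2.08 for Phe-GAA fragments). More cleavage of Phe-GAA and Trp-CCA, or longer survival of their fragments, may also explain the rise and stays an untested hypothesis, which fragment ends and lengths, a measure of fragments without reverse transcription, and decay rates would decide.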

How the results depend on the processing

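TMM within each library type and the list tests without each mouse or with a block were chosen only after the result was seen. Among the 109 results of the FTSJ1 wobble list and of the tRNAs named for the size of their change, 87 were calls. Of these calls 59 were kept under every setting that gave a value for the family, and none reversed. The table's own rows gave no such value. Among the kept calls, Ile-GAT and Ala-GGC, ribosome vs total in WT, had values in only 13 and 14 settings. The kept calls were unevenly spread. Within WT, only Cys-ACA and Pro-TGG, both for ribosome against total, lost a call under some setting. Most calls of a KO effect lost theirs under some setting, and in total tRNA only Phe-GAA kept its call under each. Over the 1651 alternative values of the 109 results, 1420 kept direction and side of the threshold, 174 lost and 22 gained a call, and 35 changed sign. Of 54 further results, those of list members with the largest change and of Glu-CTC in fragment minus total, 8 were calls, 7 of them kept under every setting and Glu-CTC lost in 13 of 16, and 22 of those not called passed in at least 1 setting. Where no cause is named, the cause was not tested.

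For total tRNA (4 calls) the count was 1 with DESeq2, 2 with all 18 libraries, 2 with total reads, 2 with total reads without Phe-GAA, 18 with the table's own entries (101 tested), and 1 to 9 with a mouse left out. For ribosome-contained tRNA (11) it was 4 with the table's own entries and 3 to 22 with a mouse left out, and for fragments (12) 7 to 14 with a mouse left out. For ribosome minus total (0) it was 2 with DESeq2 (0 higher), 7 with DESeq2's size factors and 10 with TMM within each library type. It was 2 with limma-voom (0 lower), 5 at a mean count of at least 100, 7 with the table's own entries and 11 with total reads. Without Phe-GAA it was 11, and with a mouse left out 0 to 13. For fragment minus total (16) it was 9 with DESeq2, 8 with TMM within each library type, 8 with all 18 libraries, 9 with the table's own entries, 8 without Phe-GAA, and 8 to 15 with a mouse left out. In WT the table's own entries, more of which were tested, gave 95 for ribosome against total (38; 34 to 41 with a mouse left out) and 84 for fragment against total (42; 41 to 43). Of the list tests 5 passed, 1 with an estimated correlation, 26 with fry, which does not compare a list with other tRNAs, 6 with a block (the mouse across library types, the replicate number for KO against WT) and 4 to 6 with a mouse left out. Without the FTSJ1 wobble list the correlations of KO effects were 0.54, 0.07 and -0.14.

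The sign changes among the 109 were in tRNAs that did not pass with the main settings; of the changed values, only those of Leu-CAA, fragment vs total in WT, with all 18 libraries, total reads and total reads without Phe-GAA passed. Leu-CAA, KO vs WT, total tRNA, was -0.0067 with DESeq2, -0.0066 with its size factors, -0.054 with all 18 libraries, -0.0028 without a filter and down to -0.014 with a mouse left out. Leu-TAA, KO vs WT, total tRNA, reached 0.023 and Trp-CCA, KO vs WT, ribosome-contained tRNA, -0.176 to 0.036 with a mouse left out. Leu-TAA, KO vs WT, tRNA fragments, was 0.0057 with DESeq2, 0.0058 with its size factors, 0.013 with limma-voom, 0.041 without a filter, 0.0017 with the replicate block and -0.177 to 0.147 with a mouse left out. With a mouse left out, Trp-CCA, KO effect in ribosome minus total, spanned -0.021 to 0.179 and Leu-TAA, KO effect in ribosome minus total, -0.027 to 0.179. Leu-TAA, KO effect in fragment minus total, was 0.072 with TMM within each type, 0.081 with all 18 libraries, 0.024 without Phe-GAA and -0.203 to 0.071 with a mouse left out. Leu-CAA, ribosome vs total in WT, was -0.093 with all 18 libraries, -0.036 without a filter and -0.072 to 0.093 with a mouse left out. Leu-CAA, fragment vs total in WT, was -0.254 with all 18 libraries, -0.271 with total reads and -0.307 without Phe-GAA (adjusted p = 0.0096, 0.0019 and 0.00062, edgeR), and -0.0080 at a mean count of at least 100, -0.00053 without a filter, -0.0011 with the replicate block and -0.102 to 0.057 with a mouse left out.

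WT and KO mice of the same number were not taken as paired. Low correlations cannot show that they are unpaired, since total and ribosome-contained libraries of the same mouse also gave r down to -0.34. Deviations of WT and KO mice of the same number correlated between -0.48 and 0.11, and 0 of 9 WT libraries correlated best with the KO library of their number. With that number as a block the counts for KO against WT were 6, 11 and 10: Pro-GGG (1.43, adjusted p = 4.2e-09, edgeR) and Pro-TGG (0.42, adjusted p = 0.023) gained a call in total tRNA, and Leu-AAG (adjusted p = 0.0173) was among 3 that gained one in ribosome-contained tRNA, while Ser-AGA (0.0667), Ala-AGC (0.0577) and Gly-TCC (0.0826) in ribosome-contained tRNA and Arg-CCT (0.0564) and Gly-ACC (0.0878) among fragments did not pass. Mice pair the library types, and with the mouse as a block the counts were 0, 12, 38 and 44, with no call changed among named tRNAs other than the 5 lost and iMet-CAT gained in fragment minus total, given in the report. Limiting the fits and the Phe-GAA share to nuclear tRNAs gave no value, since no mitochondrial tRNA was listed. Fragments of Leu-TAA had 33 to 66 reads per library.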

Other observations

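Tests in this part were chosen only after the results were seen, except the correlation of the long-arm share over 6 mice.

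Some fragment reads came from table entries that took a far smaller share of total tRNA libraries. Of 72 entries with at least 100 fragment reads in WT, 6 took over 30 times the share of fragment reads that they took of total reads: Glu3-CTC (392 times), Gly11-GCC (261 times), Asp3-GTC (109 times), Gly13-TCC (68.2 times), Gly10-GCC (61.5 times) and Gln5-CTG (33.3 times). Gly11-GCC had 9 reads in the 3 WT total libraries together, 0 to 5 per library, and Gly10-GCC had 31, 5 to 20 per library, so their ratios are imprecise: Gly11-GCC was at 160 times without WT mouse 1 and 461 times without WT mouse 3, and Gly10-GCC at 114 times without WT mouse 2. Entries of 1 family can differ by few bases, and how reads matching several entries were assigned is not given in the sources used here.

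The 81 table entries with a mean under 0.03% of total tRNA reads, a limit set on the total libraries alone, made up 0.239% ± 0.0185 in WT and 0.333% ± 0.0221 in KO total libraries (SD, n = 3 mice each; exact permutation p = 0.1; 73 of the 81 higher in KO). The 7 most abundant of them held 0.145% in WT and 0.180% in KO, the other 74 held 0.0941% and 0.153%, and all 81 made up 0.699% ± 0.198 and 0.619% ± 0.133 of ribosome-contained libraries (exact permutation p = 0.5, n = 3 each), and 2.13% ± 0.133 and 2.14% ± 0.0327 of fragment libraries (exact permutation p = 0.9, n = 3 each). The room left by the fall of Phe-GAA would raise every other share 1.015 times, less than the rise seen. Deeper sequencing of KO libraries stays open, since within genotype the share and the depth of the 6 total libraries had a Pearson r of -0.673 (exact permutation p = 0.306), 0.968 in WT and -0.974 in KO; against it, KO mouse 2 had 1518177 reads, within the WT range, and a share of 0.355%, above each WT library, but that is 1 library. A genotype effect on these tRNAs in each intact pool stays open too, because the ribosome-contained log2 ratio was -0.16 with an SE of 0.28.

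The median log2 fold change of long-arm tRNAs in KO ribosomes was 0.29, a list difference that passed camera with the preset correlation and not with an estimated one (adjusted p = 0.834 with an estimated correlation). A single library as the whole source of this median is argued against, since the lowest median with 1 mouse left out was 0.21, although members past the test went from 4 to 1 without any 1 of KO mouse 2, KO mouse 3, WT mouse 1, WT mouse 2 and WT mouse 3, and to 8 without KO mouse 1. A gel window shifted to longer molecules may contribute and stays open: SeC-TCA, the longest tRNA, had a log2 fold change of -0.015 on 50 to 89 reads, too few to decide (SE 0.35). A shift of each brain shared by its total and ribosome-contained libraries also stays open, with a Pearson r of 0.661 over 6 mice (exact permutation p = 0.169), a Spearman rho of 0.486 (exact permutation p = 0.356), an r of 0.582 within genotype, and an r of 0.256 without the 2 mice farthest from the median of the total share. A genotype effect on serine and leucine tRNAs in ribosomes stays open beside these.

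Regrouping the 6 mice, or within WT the 6 libraries of 3 mice, gives 10 splits into 3 and 3, so the share of splits as large as the real one cannot be under 0.05. The counts of tRNAs past the threshold, real and highest among the other splits, were 4 and 0 for total tRNA, 11 and 1 for ribosome-contained tRNA, 12 and 0 for fragments, 0 and 0 for ribosome minus total, 16 and 0 for fragment minus total, 38 and 0 for ribosome against total in WT, and 42 and 0 for fragment against total in WT. The last 2 contrasts pair the libraries of a mouse, and among the 4 splits that part all 3 pairs, the real one included, the highest other count was also 0 in each. In these 2 contrasts every other split puts both library types into the same group, which widens the spread within groups. Their counts of 0 therefore say nothing about chance. Each other split of the 6 mice likewise puts WT and KO mice into the same group, which widens the spread wherever the genotypes differ. The low counts of those splits in the genotype contrasts therefore do not decide about chance either.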
